A study of Mus musculus with 9 samples.

How the data were processed

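Gene expression was measured by RNA sequencing of mouse gastrocnemius, the large calf muscle, in 9 libraries. They formed 3 groups of 3: sedentary mice (SED), mice trained on a treadmill (AET), and mice trained in the same way that also received metformin (AET_MET). Per the labels, training ran on 5 days a week for 60 minutes a day over 8 weeks, and metformin, an oral glucose-lowering drug, was given in drinking water at 2 mg/mL. The labels number the samples within each group and do not say that each came from a separate mouse, so p-values measure the spread between these samples, which may be technical. Collection time, feeding state and library batch are not given in the sources used here. The library names share a stem within each group, so a batch that follows these names cannot be separated from any comparison. No group that received metformin without training was analysed here. An effect of metformin on the training response therefore cannot be separated from an effect of the drug alone.

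The deposited table holds RSEM expected counts per gene, which are estimated read numbers that need not be whole, with 1 column per library. STAR 2.5.3a, RSEM 1.3.0, edgeR 3.34.0 and the mouse build GRCm38 are named, without their roles, per the submitters' processing notes. The annotation release, any filter and the strand setting are not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense neighbour cannot be told apart. RSEM divides reads between near-identical copies, so pseudogenes, overlapping genes and paralogs are uncertain. Between 4.85% and 5.53% of the values of a library were not whole, and all values were rounded to whole numbers before testing.

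The table holds 55416 gene identifiers. The GENCODE M21 annotation of GRCm38 gave a symbol to 52083 of them and none to 3333, of which 63 were tested. Unmatched identifiers took 2.69% to 5.68% of the counts of a library, and 4 of them took 2.67% to 5.64%. Totals ran from 15434400 expected counts in AET_MET replicate 1 to 25355900 in AET replicate 3. They averaged 22004800 ± 384633 in SED, 24151600 ± 1551970 in AET and 19201000 ± 3337610 in AET_MET (mean ± SD, n = 3). Mitochondrial genes took 11.2% to 15.6% of the counts, and the 10 most abundant genes took 36.6% to 41.3%. Libraries of 1 group correlated at 0.975 to 0.986 in log2 CPM (counts scaled to a common library size). Their counts differed by at least 14.7 in chi-square per degree of freedom, above sampling noise, so none was merged with another as a repeat of 1 library. This does not show that they came from separate mice.

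Genes were tested with edgeR 4.0.16 in R 4.3.3, by the robust quasi-likelihood test with TMM scaling and the filterByExpr filter. A fit of all 9 libraries left 6 residual degrees of freedom and tested 13944 genes, at a common biological coefficient of variation of 0.134. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM as mean ± SD (n = 3), and changes are log2 fold changes ± SE. Gene lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and an adjusted p under 0.05. Of 47 lists, 46 had at least 3 measured genes and were tested, and 12 of the 47 were set up for cell types or tissue parts other than the fiber. The 12 include a list of neuromuscular junction and denervation genes, which fibers themselves can express. Each list was also tested with the correlation estimated from the libraries, and with fry, which asks whether the genes of a list move, on balance, one way. A higher p in the estimated test need not come from correlation between genes. The glucose uptake and insulin list in AET against SED had an estimated correlation of 0.00118, below the preset. Its camera adjusted p was 0.000566 with the preset and 0.124 with the estimate. Some genes stand in more than 1 list, among them 13 of the 20 measured glucocorticoid and FOXO targets, so list results are not independent.

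The genes named follow a rule. It took, per comparison, the 8 called genes with the largest change in each direction, with a mean of at least 1 CPM in a group, no overlap between the libraries of the groups, and an informative symbol. It also took up to 4 genes with the smallest p from each list that passed or held a called gene, and a fixed panel of 24 training and metabolism genes, of which 22 were measured. Some of these are left out for length, and some results are not reported here. Genes outside the rule are named as chosen after their values were seen. The lists, the rule, the tests and most alternatives were set before the data were examined. The length and GC correction and the slow-fiber covariate were added after seeing the data. The correction was fitted to log2 levels but applied as natural logs, so it was stronger than the fitted trend. Calls lost or turned under it may come from this excess.

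The size in AET_MET of the response seen in AET was measured on genes chosen without the SED and AET libraries it was measured in. The AET_MET libraries stayed in the fit that ranked the genes, where they entered the estimate of the spread. The genes were chosen for a response in AET, so an equally large response in other genes would also give a ratio below 1. For each of the 9 choices of 1 held-out SED and 1 held-out AET library, the 200 genes with the smallest p between the other AET and SED libraries were taken. Their mean signed log2 change was measured between the held-out AET and SED libraries, and between AET_MET and the held-out SED library. On simulated counts with a true ratio of 0.5 or 1, this ratio came out at 0.506 and 0.998. The 200 genes were chosen there from 13944, of which 1500 were changed. There AET_MET was given the AET changes at that scale, so a response in other genes was not tried.

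The gene test was tried on simulated counts with 200 changed genes. Of these, 67, 67 and 66 were changed 1.5-fold, 2-fold and 4-fold. For AET against SED, 26.9%, 68.7% and 86.4% of them were recovered with 13714 genes tested, with 10 false calls. For AET_MET against SED the shares of the changed genes were 34.3%, 68.7% and 92.4% with 13742 genes tested, with 7 false calls. For AET_MET against AET they were 47.8%, 62.7% and 89.4% with 13746 genes tested, with 9 false calls. Changes of 1.5-fold were thus often missed with 3 libraries per group.

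Alternatives covered DESeq2 1.42.0, limma-voom with and without sample weights, other scalings, other low-count filters, fits without the most abundant genes or without mitochondrial genes, fits of 2 groups, the replicate number as a block, each library left out in turn, and other thresholds. Coordinates are from GENCODE M21 on GRCm38.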

Results

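The transcriptome of gastrocnemius was compared between sedentary mice (SED), treadmill-trained mice (AET) and trained mice given metformin (AET_MET), with 3 libraries in each group. The comparisons ask how muscle gene expression differed with training, and how trained mice given metformin differed from those without it. Libraries held 15434400 to 25355900 expected counts. The first principal component of log2 CPM took 25.9% of the variance and placed SED at -28.2 ± 1.13, AET_MET at 4.43 ± 5.61 and AET at 23.8 ± 7.18 (mean ± SD, n = 3). On the second, which took 20.5%, AET_MET replicate 1, the library with the fewest counts, lay farthest out at 44.2.

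Several genes of muscle protein breakdown were lower in AET than in SED, and a gene of NAD synthesis was higher. Trim63, encoding the muscle ubiquitin ligase MuRF1, fell from 1337 ± 37.8 CPM in SED to 175 ± 29.0 CPM in AET (SD, n = 3), a log2 change of -2.93 ± 0.34 (edgeR adjusted p = 0.00319). Fbxo32, encoding the ubiquitin ligase atrogin-1, fell from 1829.6 ± 12.9 to 599.8 ± 118 CPM (log2 change -1.61 ± 0.18). Depp1, a FOXO target, had the steepest fall among the genes the rule names, from 99.1 ± 26.2 to 3.72 ± 0.860 CPM (log2 change -4.72 ± 0.53, edgeR adjusted p = 0.00368). Nmrk2, encoding a nicotinamide riboside kinase, rose from 10.01 ± 1.62 to 88.1 ± 7.60 CPM (log2 change 3.14 ± 0.27, edgeR adjusted p = 0.000706). On GRCm38 these protein-coding genes lie on chromosome 4 at 134315120 to 134329629 (Trim63), chromosome 6 at 116650609 to 116652794 (Depp1) and chromosome 10 at 81198170 to 81202051 (Nmrk2). Glul, encoding glutamine synthetase, fell from 958 ± 96.8 to 171 ± 24.9 CPM, and Ky, a gene of muscle maintenance, rose from 31.4 ± 11.8 to 134 ± 18.3 CPM.

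In all, 812 genes rose and 900 fell in AET against SED. With upper-quartile scaling 980 of 1691 calls were rises. The total of 1712 became 1125 without SED replicate 1, 957 without SED replicate 2, 934 without AET replicate 1 and 954 without AET replicate 3. Of the fixed panel, 2 genes rose and 5 fell (2 and 6 adjusted over the list alone).

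Of the 20 measured glucocorticoid and FOXO targets, 16 fell and none rose in AET against SED (19 fell adjusted over the list alone), with a mean log2 change of -1.72. They included Eif4ebp1, a repressor of translation initiation (-1.38 ± 0.09), and the transcription factor genes Klf9 (-1.09 ± 0.09) and Foxo3 (-0.94 ± 0.10). The list passed camera with the preset correlation (adjusted p = 2.55e-18), and had an adjusted p = 0.263 with an estimated correlation. Among atrophy, proteolysis and autophagy genes 10 of 24 fell (15 adjusted over the list alone), such as Ulk1, a kinase that starts autophagy (-0.76 ± 0.11), and Bnip3 (-0.65 ± 0.09). That list passed with the preset correlation and had an adjusted p = 0.122 with an estimated correlation. Of 32 proteasome subunit genes 10 fell, such as Psmb1 (-0.34 ± 0.07), and 22 fell adjusted over the list alone (adjusted p = 0.551 with an estimated correlation). Cytosolic ribosomal protein genes fell in 11 of 74 cases, Rps27 among them at -0.48 ± 0.10 (23 adjusted over the list alone, adjusted p = 0.733 with an estimated correlation). The ribosomal list no longer passed after length and GC correction, which was stronger than its fitted trend.

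Falls in AET against SED also included genes of fuel use. Pdk4, which restrains glucose oxidation by inhibiting pyruvate dehydrogenase, fell from 3320.4 ± 129 to 1228 ± 244 CPM (log2 change -1.44 ± 0.18, edgeR adjusted p = 0.00106). Ucp3, a mitochondrial carrier gene, fell from 372 ± 66.9 to 155 ± 28.4 CPM. Angptl4, encoding an inhibitor of lipoprotein lipase, fell by 2.32 ± 0.29 on the log2 scale. Glucose uptake and insulin genes fell in 8 of 23 cases with none called higher (10 adjusted over the list alone), Tbc1d1 at -0.86 ± 0.10 and Txnip at -0.63 ± 0.08 among them (adjusted p = 0.124 with an estimated correlation). Slc2a4, encoding the glucose transporter GLUT4, changed by -0.46 ± 0.11 and was no longer called without SED replicate 3 or without AET replicate 1 (adjusted p up to 0.0585 with 1 library left out). Fatty acid oxidation genes fell in 4 of 23 cases (7 adjusted over the list alone), Eci2 among them at -0.64 ± 0.10, and all 23 had a lower estimate (adjusted p = 0.775 with an estimated correlation). Antioxidant genes fell in 10 of 26 cases (14 adjusted over the list alone), with Hmox1 at -1.46 ± 0.26 and Gclm at -0.69 ± 0.12 (adjusted p = 0.551 with an estimated correlation).

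Regulators of mitochondria went both ways in AET. Of 19 such genes 2 rose and 4 fell (2 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.436). Ppargc1b, a coactivator of mitochondrial biogenesis, rose from 4.59 ± 0.399 to 8.92 ± 1.37 CPM. Its relative Ppargc1a, encoding PGC-1 alpha, rose from 31.7 ± 5.45 to 47.5 ± 3.00 CPM, a call lost without SED replicate 2, without AET replicate 3 and after length and GC correction (adjusted p up to 0.0561 with 1 library left out). Nrip1, a corepressor gene, fell by 0.58 ± 0.13, a call lost without SED replicate 1 or AET replicate 3, and Sirt1, encoding a deacetylase, by 0.43 ± 0.10, a call lost without SED replicate 2 or AET replicate 1 (adjusted p up to 0.0611 and 0.0561 with 1 library left out). The lists of complex I and of complexes II to V, which hold nuclear genes only, did not pass, nor did the TCA cycle list. Their mean log2 changes were -0.06, -0.07 and -0.05, with camera adjusted p of 0.292, 0.127 and 0.357. A list of 13 genes of mitochondrial DNA passed in no comparison. Its camera adjusted p was 0.825 here, 0.615 in AET_MET against SED and 0.977 in AET_MET against AET. Vegfa, encoding the main vessel growth factor, rose from 56.8 ± 11.5 to 97.2 ± 12.5 CPM (log2 change 0.77 ± 0.15), and its receptor gene Kdr by 1.03 ± 0.15. The angiogenesis list held 8 rises and 2 falls among 25 genes (10 and 3 adjusted over the list alone) and did not pass (camera adjusted p = 0.0787). Of 22 interferon response genes 9 rose (9 adjusted over the list alone), and the list passed upward (adjusted p = 0.551 with an estimated correlation), though not among genes of at least 5 CPM in 3 libraries.

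Of the lists of other cell types, those of Schwann cells, of tenocytes and of smooth muscle and pericytes passed in AET against SED. All 12 Schwann cell genes had a higher estimate in AET than in SED, 3 rose (9 adjusted over the list alone), and the mean log2 change was 1.00 (adjusted p = 0.551 with an estimated correlation). The 3 called were S100b, Gldn and Sox10, whose calls were kept in 4, 1 and 1 of the 9 fits without 1 library. The tenocyte list passed downward with a mean of -0.82 and no gene called over all genes or adjusted over the list alone (adjusted p = 0.811 with an estimated correlation), and did not pass without SED replicate 3, without AET replicate 1 or after length and GC correction (adjusted p up to 0.261 with 1 library left out). The smooth muscle and pericyte list passed upward with a mean of 0.47 and 3 genes called (7 rose and 1 fell adjusted over the list alone, adjusted p = 0.733 with an estimated correlation). It did not pass without SED replicate 2, without AET replicate 1 or after length and GC correction (adjusted p up to 0.0916 with 1 library left out). The endothelial list did not pass, with a mean of 0.02 and a downward camera statistic (adjusted p = 0.825), and Cldn5, a tight junction gene of endothelium, fell by 1.03 ± 0.13. The collagen and matrix list did not pass either, and its mean of -0.16 turned to 0.16, past the threshold, without SED replicate 2. Lox, encoding a collagen crosslinking enzyme, fell from 47.2 ± 5.68 to 14.7 ± 2.47 CPM.

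The clock genes divided in AET against SED. Of 19, 6 rose and 6 fell (8 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.914). Nr1d1, encoding a repressor of the clock, rose by 1.02 ± 0.10, Nr1d2 by 0.71 ± 0.09, Per3 by 1.10 ± 0.15 and Bhlhe40 by 1.41 ± 0.18 on the log2 scale. Arntl, encoding the clock activator BMAL1, and Nfil3, encoding a repressor, fell by 1.196 ± 0.24 and 2.32 ± 0.31. Both were chosen after their values were seen.

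**Figure D1:**
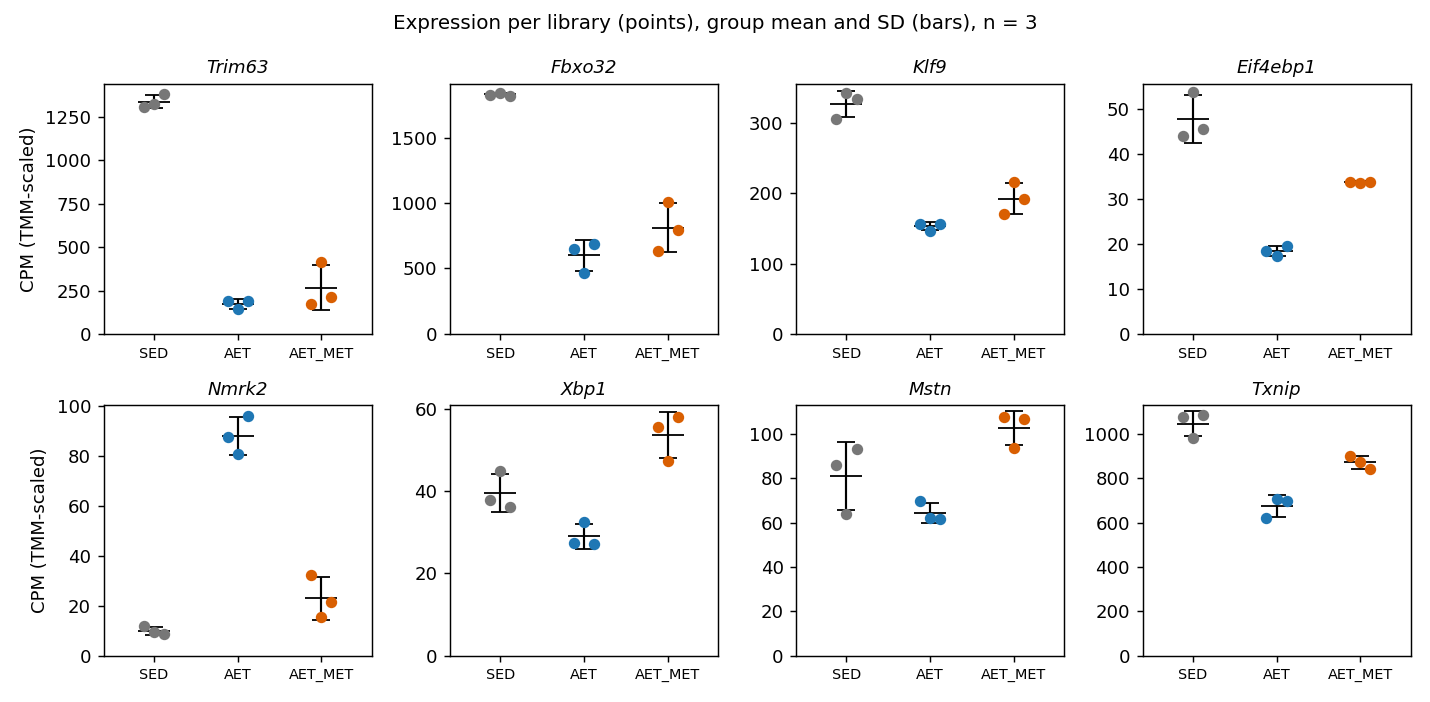
TMM-scaled CPM of 8 genes (vertical axes, each from 0) in the 3 groups, with 1 point per library and bars for mean and SD (n = 3). Nmrk2 averaged 10.01 CPM in SED, 88.1 CPM in AET and 22.9 CPM in AET_MET, and Trim63 averaged 1337, 175 and 266 CPM.

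Several genes of fatty acid use were lower in AET_MET than in SED. Pdk4 fell from 3320.4 ± 129 to 1486 ± 331 CPM in AET_MET (SD, n = 3), a log2 change of -1.16 ± 0.17 (edgeR adjusted p = 0.00776). Ucp3 fell from 372 ± 66.9 to 169 ± 29.8 CPM. Tmem140 fell from 177 ± 26.8 to 38.1 ± 10.1 CPM, and Acot1, encoding an acyl-CoA thioesterase, fell by 2.57 ± 0.39 on the log2 scale. Pthlh, encoding parathyroid hormone-related protein, rose by 2.10 ± 0.28 and the clock gene Per3 by 1.23 ± 0.15. Trim63 stood at 266 ± 131 CPM, with a log2 change of -2.33 ± 0.33 against SED. Its call was lost without SED replicate 2, without SED replicate 3 and without AET_MET replicate 3 (adjusted p up to 0.0772 with 1 library left out).

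In all, 303 genes rose and 337 fell in AET_MET against SED. With library sizes alone as the scaling, which moved the median of all genes by 0.09998 (log2), 684 of 860 calls were rises. The total of 640 became 417, 253 and 329 without SED replicate 1, 2 or 3, 181 without AET_MET replicate 1, 141 without AET_MET replicate 3, and 7 with the slow-fiber level as a covariate. Of the fixed panel, 0 rose and 2 fell (2 and 7 adjusted over the list alone).

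Fatty acid oxidation genes fell in 10 of 23 cases in AET_MET against SED, with none higher (21 adjusted over the list alone) and a mean log2 change of -0.50 (adjusted p = 0.460 with an estimated correlation). Of the TCA cycle genes 2 of 23 fell (7 adjusted over the list alone), and all 23 had a lower estimate (adjusted p = 0.460 with an estimated correlation). The lists of complex I and of complexes II to V passed downward, with mean log2 changes of -0.19 and -0.21 and 1 gene called in each (0 and 3 adjusted over the list alone). Both had an adjusted p = 0.460 with an estimated correlation, and complex I no longer passed after length and GC correction. The slow-fiber list passed downward too, with a mean of -0.86 and no gene called, either over all genes or adjusted over the list alone (adjusted p = 0.460 with an estimated correlation). Its level averaged 5.52 ± 0.17 log2 CPM in SED, 5.06 ± 0.68 in AET and 4.28 ± 0.95 in AET_MET (SD, n = 3).

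Glucocorticoid and FOXO targets fell in 11 of 20 cases in AET_MET against SED (16 adjusted over the list alone), with a mean of -1.15 (adjusted p = 0.284 with an estimated correlation). They included Klf9 (-0.76 ± 0.09) and Sesn1, a stress-response regulator (-1.65 ± 0.19). Of the atrophy list 8 of 24 fell, among them Ctsl, encoding the lysosomal protease cathepsin L (-0.73 ± 0.10), and Gabarapl1 (-1.15 ± 0.16). Adjusted over the list alone, 11 fell and 1 rose (adjusted p = 0.284 with an estimated correlation). Immediate early genes fell in 8 of 26 cases, Klf10 at -1.14 ± 0.14 and Maff at -1.50 ± 0.24, and 1 rose (12 and 1 adjusted over the list alone, adjusted p = 0.460 with an estimated correlation). Collagen and matrix genes fell in 6 of 26 cases (9 adjusted over the list alone), Col1a2 from 219 ± 46.2 to 94.6 ± 5.95 CPM and Sparc by 0.66 ± 0.10 on the log2 scale (adjusted p = 0.460 with an estimated correlation). The tenocyte list passed downward beside them, with a mean of -1.31 and no gene called (3 adjusted over the list alone, adjusted p = 0.460 with an estimated correlation). Vegfa and Ppargc1a were not called in AET_MET against SED, with log2 changes of 0.23 ± 0.15 and 0.34 ± 0.13.

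**Figure D2:**
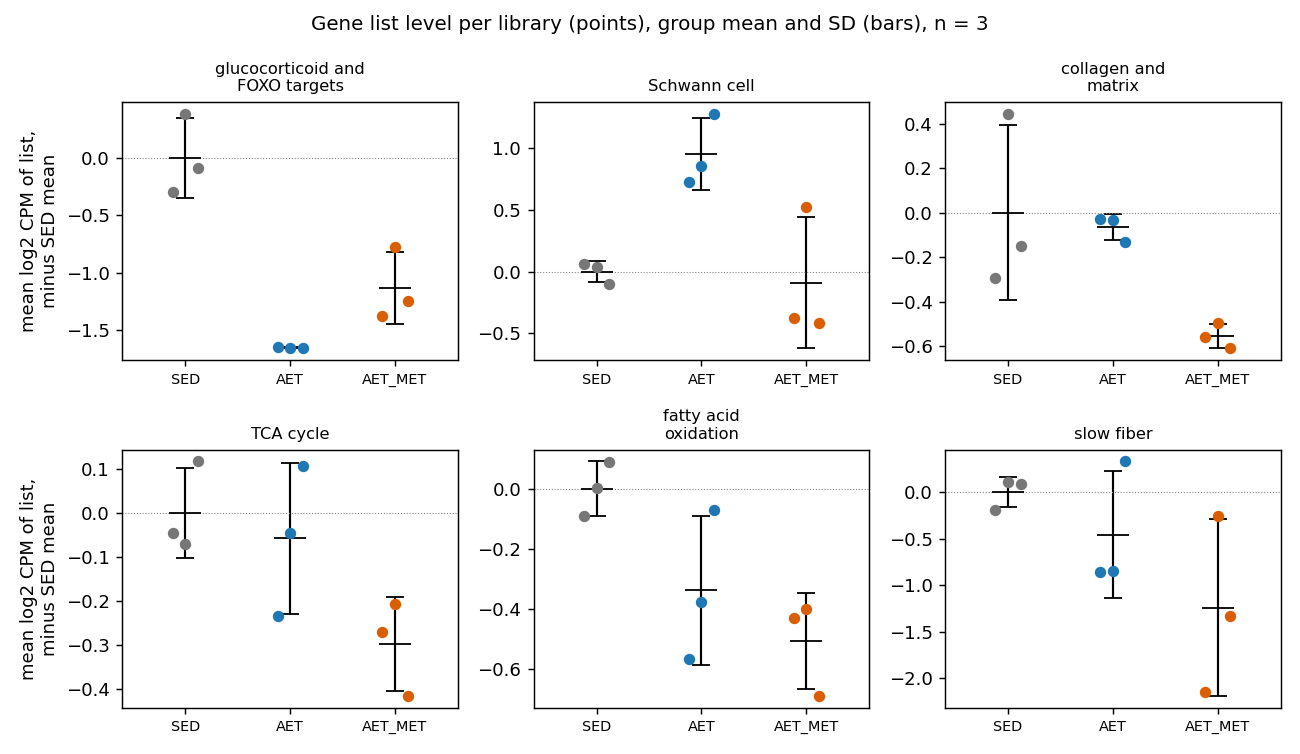
Mean log2 CPM of 6 gene lists minus the SED mean (vertical axes, each with its own range), with 1 point per library and bars for mean and SD (n = 3). The glucocorticoid and FOXO targets lay lower in every trained library than in every SED library, and the slow-fiber list ran from -2.15 in AET_MET replicate 1 to 0.33 in AET replicate 3.

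The 2 training comparisons were set beside each other on the genes called in AET against SED. Of the 1712, 91.0% had the same sign in AET_MET against SED and 394 were also called there. Shared controls alone would give much of this agreement in simulation. All 9 libraries were drawn at the SED means, each gene independently, and both unchanged groups were compared with the same simulated SED libraries. There, as many genes with the smallest p had the same sign in 85.8% of cases on average and at most 87.7%, a value added after seeing the data. Genes in the data are correlated, so the range of the simulations may be too narrow. In both comparisons 172 genes rose and 222 fell, and 3 were called in opposite directions. Independent lists would share 17.6 and 21.8 genes, but these lists are not independent, since they share the SED libraries. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.568 (Spearman's rho 0.558). In these 20 simulations r averaged 0.484 and reached 0.569, above the observed r. At most 7 genes were called for AET and 8 for AET_MET in a simulation, and at most 2 in both. So few calls give no baseline for the 394 shared ones. Over all genes 69.0% had the same sign, against 66.6% in the simulations. The covariance was 0.131 and its simulated mean 0.0437, a difference of 0.0869. The 3 SED libraries cannot be split into 2 sets of at least 2 each, so part of the excess may come from the shared controls.

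On genes chosen for their response in AET, without the held-out SED and AET libraries, the AET_MET change was 0.593 of that in AET. The ratio was 0.447 to 0.670 over the 9 choices of held-out libraries, all below 1. An equally large response in other genes would also give a ratio below 1, so the value describes AET-responsive genes alone. The mean signed log2 change was 0.75 in held-out AET libraries and 0.45 in AET_MET. The 9 choices share libraries, so their range is a description and carries no p-value.

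**Figure D3:**
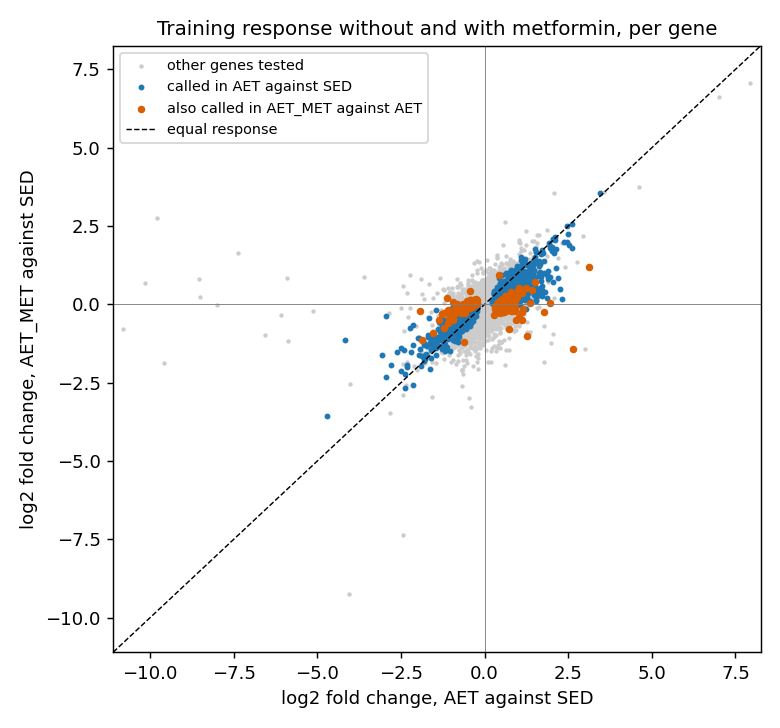
Log2 fold change of AET against SED (horizontal axis) and of AET_MET against SED (vertical axis) for all 13944 genes tested, 1 point per gene, with the line of equal response dashed. Blue points were called in AET against SED, orange points also in AET_MET against AET, and r across all genes is 0.568.

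Metformin during training was tested directly by AET_MET against AET. Nmrk2 was lower with metformin, at 22.9 ± 8.55 CPM against 88.1 ± 7.60 CPM in AET (SD, n = 3), a log2 change of -1.95 ± 0.25 (edgeR adjusted p = 0.0162). Eif4ebp1 was higher, at 33.8 ± 0.119 against 18.4 ± 1.17 CPM (log2 change 0.87 ± 0.09, edgeR adjusted p = 0.00172). Xbp1, encoding a transcription factor of the unfolded protein response, was higher by 0.89 ± 0.11, Cep85l by 0.96 ± 0.11 and Pfkfb4, encoding a regulator of glycolysis, by 0.71 ± 0.09. Ndufa8, encoding a complex I subunit, was lower, at 51.1 ± 1.22 against 78.3 ± 7.82 CPM. Mstn, encoding the growth inhibitor myostatin, stood at 103 ± 7.76 against 64.5 ± 4.61 CPM (log2 change 0.67 ± 0.12, edgeR adjusted p = 0.0210). It lies on chromosome 1 at 53061640 to 53068079 (GRCm38). The Nmrk2 call was lost without AET replicate 1, AET replicate 3 or AET_MET replicate 3, and the Mstn call without any 1 of AET replicates 1, 2 and 3 and AET_MET replicates 1 and 3. With 1 library left out their adjusted p reached 0.0880 and 0.104.

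In all, 231 genes were higher and 247 lower in AET_MET than in AET. With library sizes alone, which moved the median of all genes by 0.0888 (log2), 611 of 767 calls were rises. The total of 478 became 104 without AET replicate 1, 34 without AET replicate 3, and 85, 151 and 23 without AET_MET replicate 1, 2 or 3. Of the 65 called genes that the rule names, 5 were called in each of the 9 fits without 1 library, and these were Eif4ebp1, Xbp1, Cep85l, Pfkfb4 and Ndufa8. With the slow-fiber level as a covariate 26 genes were called, and Ndufa8 was not among them. The other examples given for this comparison each lost the call in at least 1 of those fits. Of the genes called in AET against SED, 240 were called in the opposite direction in AET_MET against AET and 2 in the same direction, and these comparisons share the AET libraries, which raises the first of these counts. Of the fixed panel, 2 genes were higher and 0 lower (2 and 1 adjusted over the list alone).

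Collagen and matrix genes fell in 8 of 26 cases in AET_MET against AET, with none called higher (13 adjusted over the list alone) and a mean log2 change of -0.49. The list passed with the preset correlation and had an adjusted p = 0.733 with an estimated correlation. Examples were Col15a1 (-0.82 ± 0.14), Col6a1 (-0.57 ± 0.11) and Col4a2 (-0.53 ± 0.10). The Schwann cell list passed downward beside them with a mean of -1.01, 1 gene called and 7 adjusted over the list alone (adjusted p = 0.733 with an estimated correlation). The smooth muscle and pericyte list and the macrophage list also passed downward, with means of -0.43 and -0.26 and 0 and 0 genes called (5 and 0 adjusted over the list alone, adjusted p = 0.733 with an estimated correlation). The first did not pass without AET_MET replicate 3 or after length and GC correction, nor the second among genes of at least 5 CPM in 3 libraries, with limma-voom sample weights, without AET replicate 1 or 2 or AET_MET replicate 1 or 2, and neither with the slow-fiber covariate (adjusted p up to 0.0534 and 0.309 with 1 library left out). Of the complex I genes 4 of 36 fell, with Ndufb10 at -0.53 ± 0.09 and Ndufa5 at -0.41 ± 0.09 beside Ndufa8 (11 fell and 1 rose adjusted over the list alone). TCA cycle genes fell in 2 of 23 cases, Dld (-0.45 ± 0.09) and Dlst (-0.42 ± 0.09), and in complexes II to V Cycs fell (-0.40 ± 0.09). Adjusted over the list alone, 8 and 8 genes of these lists fell. The lists of the TCA cycle, of complex I and of complexes II to V passed with the preset correlation and had an adjusted p = 0.733 with an estimated correlation. The lists of complex I and of complexes II to V no longer passed without AET replicate 2, without AET replicate 3 or with the slow-fiber covariate, with adjusted p up to 0.143 and 0.151 with 1 library left out.

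Lists that were lower in AET than in SED stood higher in AET_MET than in AET in several cases. Glucocorticoid and FOXO targets rose in 2 of 20 cases (4 adjusted over the list alone), with all 20 estimates higher and a mean of 0.57. Cytosolic ribosomal protein genes rose in 5 of 74 cases, Rps20 at 0.42 ± 0.08 among them (6 rose and 1 fell adjusted over the list alone). Atrophy genes rose in 2 of 24 cases (6 adjusted over the list alone). All 3 lists passed upward and had an adjusted p = 0.733 with an estimated correlation. These comparisons share the AET libraries, which favours opposite signs, and no simulated value was computed for lists. The fatty acid oxidation list, lower in AET than in SED, was lower again in AET_MET than in AET, with a mean of -0.18 and 1 gene called (2 adjusted over the list alone, adjusted p = 0.733 with an estimated correlation). It did not pass without AET replicate 3, without AET_MET replicate 3 or with the slow-fiber covariate (adjusted p up to 0.428 with 1 library left out). The tenocyte list also had a negative mean again (-0.49) and did not pass (camera adjusted p = 0.0625). The interferon and angiogenesis lists passed downward, with means of -0.33 and -0.23 and 0 and 2 genes called (0 and 3 adjusted over the list alone), again with an adjusted p = 0.733 with an estimated correlation, and the interferon list did not pass among genes of at least 5 CPM in 3 libraries. Vegfa did not pass, at -0.54 ± 0.15.

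Some large changes are of uncertain identity. RPS10-NUDT3, on chromosome 17 at 27580780 to 27635222 (GRCm38), is a gene that overlaps others in the annotation and stood at 10.2 ± 0.569 CPM in AET and 0.556 ± 0.771 CPM in AET_MET. Fabp3-ps1, a pseudogene that can share reads with Fabp3, differed by -1.85 ± 0.33 between these groups. The mitochondrial gene mt-Nd6, on the opposite strand to most genes of that genome, stood at 222 ± 76.7 CPM in AET and 66.8 ± 5.41 CPM in AET_MET, and its call was lost in 6 of the 9 fits without 1 library.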

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

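The tests of clock phase, scaling, length and GC content, nerve tissue, fiber share, slow-fiber level and the shallowest library were chosen only after the results were seen; the other splits of the libraries were planned.

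Each result here stood out because AET_MET differed from AET in the direct test. Without a group given metformin but no training, a changed training response and an effect of metformin alone cannot be told apart. Lists lower with metformin, by their mean log2 difference, were collagen and matrix (-0.49), Schwann cell (-1.01), TCA cycle (-0.25), interferon response (-0.33), complexes II to V (-0.14), angiogenesis (-0.23), complex I (-0.12) and fatty acid oxidation (-0.18). So were smooth muscle and pericyte (-0.43), sarcomere structure (-0.26), slow fiber (-0.57), fast IIA and IIX fiber (-0.79), cell cycle (-0.43) and macrophage (-0.26). Lists higher with metformin were glucocorticoid and FOXO targets (0.57), cytosolic ribosome (0.10), atrophy genes (0.18) and proteasome (0.11). All 18 had an adjusted p = 0.733 with an estimated correlation, and 8 of them passed in each of the 9 fits without 1 library. The slow-fiber list and the fast IIA and IIX list did not pass in a fit of the 2 groups alone, nor did the latter with the replicate block. Among genes, the log2 difference was -1.95 for Nmrk2, -1.94 for Sept3, 0.67 for Mstn and 0.37 for Txnip. It was -4.08 for RPS10-NUDT3 and -1.85 for Fabp3-ps1, whose reads can be shared with other genes.

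Splits of 6 libraries into 3 and 3 number 10, so the share of splits with a result as large as the real one is never under 0.1. Each other split mixes the real groups, so a difference between them, whatever its cause, becomes spread and lowers the number of gene calls. The gene calls of those splits are therefore no measure of what unchanged groups would give. For AET against SED, 1 split, the real one, gave as many genes (1712 real, 0 at most in the others), and 4 splits gave as many lists (19 real, 22 at most in the others). For AET_MET against SED the splits were 1 for genes (640 real, 1 at most in the others) and 3 for lists (23 real, 23 at most in the others). For AET_MET against AET they were 1 for genes (478 real, 0 at most in the others) and 3 for lists (18 real, 22 at most in the others).

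Glucocorticoid and FOXO targets were lower in AET than in SED, with a mean change of -1.72 (log2), and higher in AET_MET than in AET, by 0.57. Against scaling and against length and GC bias as the cause of the first, its mean was at most -1.69 under 3 other scalings and -1.72 after the correction, with the list test passed at the preset correlation (reported list, adjusted p = 0.263 with an estimated correlation). Collection at another clock phase stays open. An index of 12 clock genes was higher in AET than in SED by 2.03 (log2), above the sum of the SDs of the groups (0.25). Nr1d1, Nr1d2, Per3, Arntl and Nfil3 are among its genes and were already seen to differ, so this separation is no independent support. For the second, the index lay 0.12 higher in AET_MET than in AET, away from SED and so against a phase nearer that of SED, but within the sum of their SDs (0.79), so clock phase and metformin cannot be told apart with 3 libraries a group. Training and metformin remain open biological explanations, untested.

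The Schwann cell list was higher in AET than in SED by a mean of 1.00 (log2). A lower share of muscle fibers would raise all other cell types alike, whereas this list rose over the endothelial list by at least 0.66 in each AET library. The smooth muscle and adipocyte lists, at 0.68 and 0.66 over the SED mean, lay near the Schwann list (0.73) in AET replicate 1, so a rise of some other cell types there stays open. Length and GC correction left a mean of 1.00, with the list test passed at the preset correlation (reported list, adjusted p = 0.551 with an estimated correlation). More nerve tissue in the sampled piece stays open. The within-group deviations of Mbp, Prx and Pmp22 moved together over the 9 libraries (lowest pairwise r 0.970). These genes were chosen after seeing the data and are fewer than first set. Genes of 1 cell type can move together for other reasons, and deviations from group means leave out the difference between groups. This r therefore cannot decide the question. Training as a biological cause stays open, untested.

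Genes of the TCA cycle and nuclear genes of the respiratory complexes were lower in AET_MET than in AET. Over 95 genes the mean change was -0.16, with 77 lower and 7 called (camera p = 3.18e-07 at the preset and 0.427 at an estimated correlation). The groups overlapped, since the level of these genes relative to the SED mean was -0.27 in AET replicate 1 and -0.20 and -0.16 in AET_MET replicates 1 and 2. Against the shallowest library and against length and GC bias as the cause, the mean was -0.16 without AET_MET replicate 1 and -0.15 after the correction, and the list test was passed both times at the preset correlation, with 2 and 15 genes called. With the slow-fiber level as a covariate the mean was -0.0924, 58.7% of its size, with a camera p of 0.00165 and 0 genes called. Slow-fiber share and metformin therefore cannot be told apart, because the level differs both between and within the groups. Metformin as a biological cause stays open, untested. Outside these 95 genes, the list of 13 genes of mitochondrial DNA did not pass in AET_MET against AET (camera adjusted p = 0.977). Its mean log2 change was 0.10 and its median -0.11, with 5 estimates higher and 8 lower.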

How the results depend on the processing

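The length and GC correction and the slow-fiber covariate were chosen after seeing the data, as was restricting r to the genes tested in the fit of all 9 libraries; the other alternatives were planned, and the cause of each change was not tested unless fewer samples or a threshold gives it. For AET against SED (1712 genes) the slow-fiber covariate gave 1114, an adjusted p under 0.10 gave 2742, a log2 change of at least 0.58 gave 827, and fits without 1 library gave 934 to 1509. For AET_MET against SED (640) these were 7, 1217, 320 and 141 to 655. For AET_MET against AET (478) they were 26, 1243, 168 and 23 to 461, and DESeq2 gave 888, library sizes alone 767 and no low-count filter 731. Of lists, 19, 23 and 18 passed in the 3 comparisons, in the same order 0, 0 and 0 with an estimated correlation and 10, 5 and 0 by fry. Fits without 1 library gave 14 to 25, 22 to 26 and 11 to 21 lists. Length and GC correction left 12 lists in AET against SED, and the slow-fiber covariate 10 in AET_MET against AET. The length and GC correction was stronger than its fitted trend, so calls lost or turned under it may come from the excess. Lists that passed in either fit and whose camera direction turned were collagen in AET against SED without SED replicate 2 (list mean 0.16, otherwise down to -0.32 with 1 library left out), cytosolic ribosome in AET_MET against SED after length and GC correction (0.00391) and Schwann cell in AET_MET against SED with the slow-fiber covariate (0.48). Directions also turned in 165 cases of a list or named gene called in neither fit. No named gene called in either fit changed sign. The r between the training responses was 0.727 with that covariate and 0.479 to 0.639 without 1 library, and the held-out ratio was 0.571 to 0.603 with other numbers of genes or a stricter filter. Whether the replicate numbers pair the samples is not settled by these values. In deviations from the group mean, 2 of 9 same-number pairs correlated above 0.1, and 4 of 9 samples correlated best with their own number. Same-number pairs averaged 0.0369 and other pairs -0.0183, a difference too small to show or exclude pairing. The replicate block gave 1530, 535 and 358 genes.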

Other observations

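The results given here come from planned list and gene tests, except that Malat1 and the library with values nearest SED were chosen only after their values were seen.

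Further lists passed in AET against SED. Of 22 genes of the integrated stress response 6 fell (8 adjusted over the list alone), Atf4, its central transcription factor, by 0.64 ± 0.09 on the log2 scale and Cebpb by 1.55 ± 0.15 (adjusted p = 0.469 with an estimated correlation). Genes of the AMPK and mTOR pathways fell in 5 of 25 cases (6 adjusted over the list alone), with a median log2 change of -0.0648 and 9 estimates higher. Sesn1, at -1.88 ± 0.19, also counts among the glucocorticoid and FOXO targets. The AMPK and mTOR list had an adjusted p = 0.469 with an estimated correlation, and its call was lost among genes of at least 5 CPM in 3 libraries. Glycolysis and glycogen genes fell in 5 of 27 cases (6 adjusted over the list alone), with Slc16a3, encoding a lactate exporter, at -0.78 ± 0.12 (adjusted p = 0.551 with an estimated correlation), a list call lost after length and GC correction. Calm2, encoding calmodulin, rose by 1.19 ± 0.14 in AET and by 1.05 ± 0.14 in AET_MET against SED, while the calcium handling list did not pass in either (camera adjusted p = 0.649 and 0.0871). Gadd45a, a stress-response gene also used as a marker of denervation, fell by 1.43 ± 0.22 in AET against SED.

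In AET_MET against SED, 8 of 19 clock genes rose and 2 fell (9 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0871). Nr1d2 rose by 0.73 ± 0.09 and Bhlhe41 by 0.93 ± 0.15 there. Branched-chain amino acid genes fell in 5 of 17 cases (7 adjusted over the list alone), with all 17 estimates lower (adjusted p = 0.460 with an estimated correlation). The fiber-type genes Myh1, Myh2, Myh4 and Myh7 were not called in any comparison. Myh7, of slow fibers, stood at 285 ± 35.8, 249.7 ± 248 and 122 ± 133 CPM in SED, AET and AET_MET (SD, n = 3), and Myh4, of fast fibers, at 75774 ± 7385, 76773 ± 11462 and 74200 ± 6614 CPM.

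The nuclear RNA Malat1 stood at 1149.6 ± 68.8 CPM in SED, 2303 ± 55.1 CPM in AET and 1593 ± 124 CPM in AET_MET, and how this bears on the list changes was not examined. The glucocorticoid and FOXO level, relative to the SED mean, was -1.37, -0.78 and -1.24 (log2) in AET_MET replicates 1, 2 and 3. AET_MET replicate 2 thus lay nearest SED, and its Schwann cell level of 0.53 lay above those of the other AET_MET libraries, at -0.37 and -0.42.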
